A study of Mus musculus with 5 samples.

How the data were processed

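Viable CD45-positive cells of EO771 tumors were sorted and sequenced by the authors with droplet 3' single-cell chemistry, as 1 library for each of 5 groups, each from 8 pooled tumors. The deposited matrices hold UMI count values per gene and barcode, written by Cell Ranger 6.1.1 per the file headers, and the submitters' processing notes name Seurat 4.0.5 and the GRCm38 genome. Only the deposited count matrices, with 27998 genes and 55570 barcodes in all, were used, and no normalized value of the authors entered. Total UMIs per library ran from 51186113 to 69143410 and summed to 308331473. Median genes per barcode were 1564, 1705, 1703, 1257 and 1500 for the untreated library, radiation and combination of tumor 1, and radiation and combination of tumor 2. The version of the gene annotation behind the matrices is not given in the sources used here. Gene positions were taken from GENCODE vM21 on GRCm38, with 1-based coordinates.

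The groups, comparisons, cell type markers, gene lists, size rule and alternatives were fixed before the data were examined. In each library the barcodes with the highest Scrublet scores were removed as doublets, at 0.8% of barcodes per 1000 barcodes, which took out 5144 of 55570 (9.26%). Cells with under 200 genes or over 15% mitochondrial UMIs were left out, and 44795 cells were kept. Counts were scaled to 10000 per cell and logged, 2000 highly variable genes were chosen across libraries, and cells were clustered on 30 principal components and 15 neighbors by Leiden at resolution 1, without batch correction. T and NK cells were clustered again with 1000 variable genes. Clusters were named from 130 marker genes of 22 classes, of which 123 were in the feature table. Ighm, Iglv1, Trac, Trdc, Tcrg-C1, Tcrg-C2 and Tcrg-C4 were not in it, nor was the list gene Mx2. A marker counted at 1.5 times its level in all other cells and detection in 10% of the cluster's cells, and a class needed 3 such markers.

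Some naming rules were set after the clusters had been seen. A cluster with more leading genes from another lineage, or with few UMIs and no own marker among its 10 leading genes, stayed unnamed, and a T cluster whose CD8 and CD4 marker means were closer than 0.5 on the log2 scale was called mixed T. Shares are given in the order untreated, radiation tumor 1, combination tumor 1, radiation tumor 2, combination tumor 2. A T or NK sub-cluster also stayed unnamed if, among these cells alone, its best class was not of T, NK or innate lymphoid cells. Such sub-clusters are called myeloid-marker sub-clusters, though the rule does not require that class to be myeloid. They were T sub-clusters 7 and 15, which held 0.293%, 0.078%, 0.016%, 0.239% and 0.095%, and 0.126%, 0.101%, 0.981%, 0.094% and 0.107% of cells. Mixed T cells held 0.251%, 0.123%, 0.080%, 2.87% and 0.369%. Unnamed clusters held 14.4%, 13.7%, 13.9%, 12.0% and 15.5%. Among them cluster 13, led by Ace, Ear2 and Adgre4, held 8.31%, 5.95%, 5.98%, 5.42% and 5.00%, and cluster 15, with few UMIs per cell, 3.96%, 5.97%, 5.93%, 4.25% and 4.41%.

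Shares are percent of kept cells with Clopper-Pearson intervals, and ratios of shares have Katz log intervals. UMIs were summed over the cells of a class in each library for 7 classes with at least 50 cells in both libraries, and gene levels are CPM of that sum. A gene met the size rule with a ratio of at least 1.5, at least 50 CPM and 20 UMIs in the higher library, and an exact conditional binomial 95% interval that excluded 1, and is called higher or lower by that rule. These intervals treat UMIs as independent and so are too narrow where few cells hold most UMIs, which is why the share of the largest cell is given for some genes. No test between groups and no p-value was computed, since each group has 1 library. The 6 comparisons were radiation over untreated, combination over untreated and combination over radiation in tumor 1, combination over radiation in tumor 2, and tumor 2 over tumor 1 for each treatment.

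The 19 gene lists were type I interferon response, interferon-gamma response, MHC class I presentation, MHC class II presentation, inflammatory macrophage, alternatively activated macrophage, lipid-associated macrophage, complement component 1q, hypoxia and glycolysis, myeloid chemokine, cell cycle, p53 and DNA damage response, dissociation stress and immediate early, neutrophil activation, cytotoxic effector, T-cell checkpoint and exhaustion, naive and memory T-cell, Treg effector, and Th1 and costimulation. A member counted as measured at 20 CPM in the higher library. The median log2 ratio of a list was placed among 10000 random lists of the same size, drawn from genes in the same of 20 bins of level. The random genes were drawn independently, so a percentile takes no account of list members that move together. It describes these libraries and is not a test. Genes were named if they were among the 4 largest ratios of a list that met the size rule, or among the 5 highest or lowest of all genes in macrophage-like cells, the largest myeloid class, or in CD8 T-like cells. Ribosomal, mitochondrial, hemoglobin, receptor segment and unnamed predicted genes were left out of that ranking. The antibody target and its partners were read in every case, and genes that lead a cluster discussed are named as labels of it. Not every gene named by this rule is reported here.

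The size rule and the list medians were tested on simulated data made by Poisson draws from the class sums with known changes, which hold no spread between cells or mice. Of genes changed 2-fold and 4-fold, 100 of 100 each were recovered in the macrophage and in the CD8 T setting, and 0 of 2572 and 0 of 2611 unchanged genes were called. The changed genes were drawn at 2 times the limit of 50 CPM or more. The settings were radiation over untreated in tumor 1 and combination over radiation in tumor 2, which hold many UMIs. Treg-like and neutrophil-like cells and CD8 T-like cells of tumor 1, with far fewer UMIs, were not simulated. The result does not cover them. The alternatives tried were no doublet removal, 500 genes and 10% mitochondrial UMIs, no cell filter, Leiden resolution 0.5 and 2, 4000 variable genes, classes from marker UMIs without clustering, TMM factors, cells of equal weight, cells thinned to 1000 UMIs, 10 CPM, a ratio of 2 and lists at 5 CPM. Added after the data were seen were shares without B-like and naive-led cells, shares with the myeloid-marker sub-clusters kept, and CD8 T-like gene levels and list medians without the naive-led sub-cluster. Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors, were used.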

Results

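Viable CD45-positive cells, which include the immune cells of a tumor, were profiled by droplet single-cell RNA sequencing from tumors of EO771, a mouse mammary carcinoma line, grown under the skin of female C57BL/6 mice. Each mouse carried a tumor in the right hind leg and another in the left flank, and tumors were collected on day 18. Each of the 5 groups was 1 library made from 8 pooled tumors. The groups were tumor 1 of untreated mice, tumors 1 and 2 after radiation alone, and tumors 1 and 2 after radiation with an antibody against CTLA4, an inhibitory receptor of T cells. The series title names carbon ions as the radiation and the immune response to its combination with CTLA4 blockade as the subject. The labels do not say which tumor was irradiated or which site a tumor number stands for. The libraries are called untreated, radiation and combination below, with the tumor number.

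The untreated library held 11185 barcodes with 58828247 UMIs, the radiation library of tumor 1 10690 with 67093077, the combination library of tumor 1 7823 with 51186113, the radiation library of tumor 2 14895 with 69143410 and the combination library of tumor 2 10977 with 62080626. Median UMIs per barcode were 3905, 4766.5, 4675, 3115 and 3671 in that order. After filters and removal of predicted doublets, 9558, 8919, 6218, 11707 and 8393 cells remained. With 1 library per group there was no replicate spread and no test, and the intervals, all at 95%, cover the counting of cells or UMIs only and not the variation between mice. Genes are called higher or lower by a fixed rule of size, and cell classes are named X-like because they rest on marker genes of clusters.

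Radiation was first compared with no treatment in tumor 1. Among the CD45-sorted cells, CD8 T-like cells, the cytotoxic T lineage, made up 2.89% after radiation and 9.90% without treatment, a 3.42-fold lower share (ratio 0.292, interval 0.255 to 0.334). CD4 T-like cells were 3.41-fold lower (0.258% against 0.879%; ratio interval 0.185 to 0.465) and Treg-like cells, the regulatory T cells, 2.05-fold lower (1.74% against 3.56%; ratio interval 0.405 to 0.589). NK-like cells were 2.73-fold higher (8.35% against 3.06%; 2.40 to 3.12) and neutrophil-like cells 2.83-fold higher (5.34% against 1.88%; 2.39 to 3.36). Macrophage-like cells made up 35.6% against 30.3% (ratio 1.18, 1.13 to 1.22) and monocyte-like cells 23.6% against 26.8% (ratio 0.879, 0.836 to 0.924). The B-like ratio of 0.748 had an interval from 0.51 to 1.10. It was 0.704 (0.498 to 0.994) with no doublets removed and 0.623 (0.403 to 0.962) with stricter cell filters. The shares of conventional dendritic cells of both types differed by less than counting error. Migratory dendritic cells, a separate class, were lower in share, with 187 of 8919 cells after radiation and 259 of 9558 without treatment. Unnamed clusters held 14.4% of cells without treatment and 13.7% after radiation. The macrophage-like ratio reached 2.65 with no filter on cells, the monocyte-like ratio changed direction to 1.17 with 4000 variable genes, and the CD8 T-like ratio fell to 0.143 with stricter cell filters. Taken from marker UMIs with no clustering, the neutrophil-like ratio was 1.29 and the interval of the Treg-like ratio, 0.772, ran from 0.565 to 1.06.

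**Figure D1:**
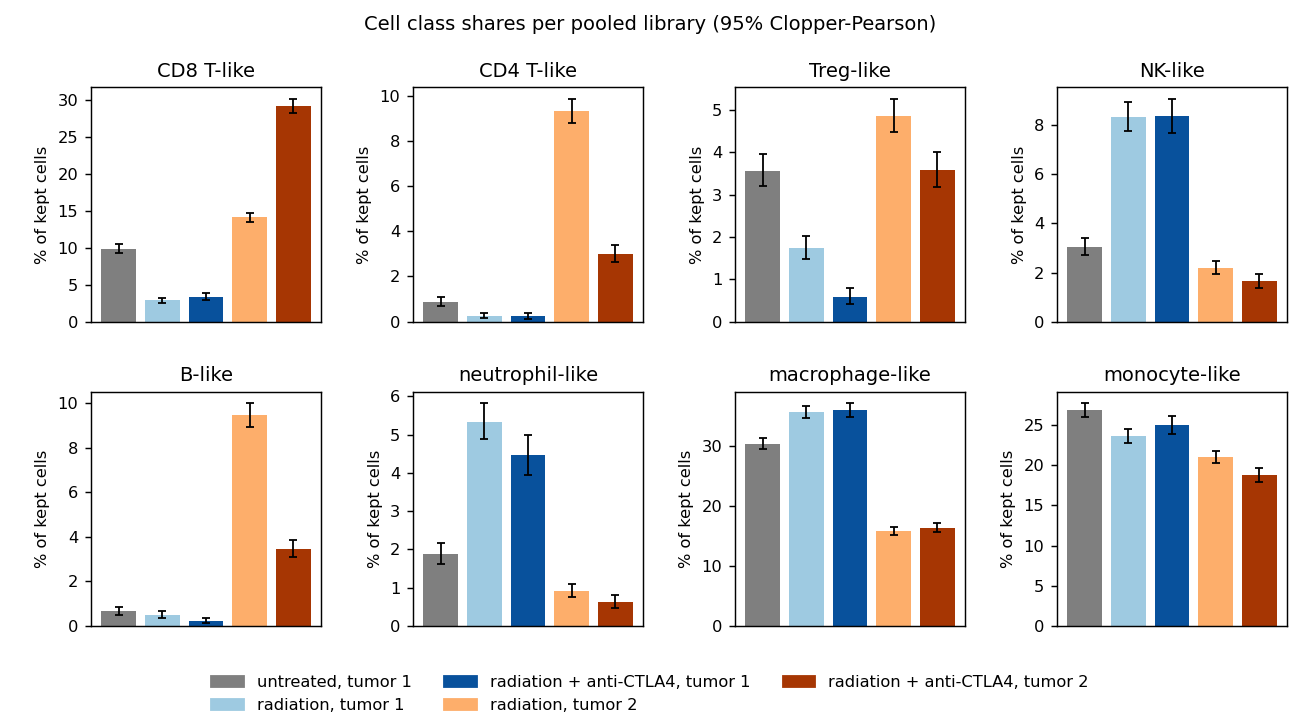
Bars show the percent of kept cells in each class per pooled library, with 95% Clopper-Pearson intervals that cover counting error only. CD8 T-like cells stand at 9.90%, 2.89%, 3.36%, 14.1% and 29.3% in the order untreated, radiation and combination of tumor 1, then radiation and combination of tumor 2.

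Macrophage-like cells of tumor 1 after radiation carried more chemokine RNA and less RNA for antigen presentation than those without treatment. Of 12 chemokine genes measured, 9 were higher and 0 lower (median log2 ratio 1.91, percentile 100 among 10000 random lists). Random lists held genes drawn independently, so percentiles here and below take no account of list members that move together. Cxcl1, a neutrophil attractant, rose 12.0-fold (10.1 to 14.3), Cxcl3 8.16-fold (7.61 to 8.75), Ccl12, a monocyte attractant, 4.74-fold (4.62 to 4.87) and Cxcl2 from 576 to 2619 CPM, 4.55-fold. Genes of alternatively activated macrophages were higher in 4 of 6 (median 1.32, percentile 100), led by Arg1, the arginase that degrades arginine, at 65 against 305 CPM (4.70-fold, 4.43 to 4.99). Folr2, a folate receptor, was 4.26-fold higher (3.96 to 4.59), Ccl8 3.45-fold and Mrc1, the mannose receptor, 1.81-fold. The largest ratio was that of Areg, an epidermal growth factor receptor ligand, at 12.4-fold (10.6 to 14.5).

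MHC class II genes were lower in 5 of 7 macrophage members (median -0.76, percentile 0.0). H2-Aa fell from 2761 to 1414 CPM (1.95-fold lower, 1.93 to 1.98), and H2-Ab1 and H2-Eb1, which encode class II chains as well, were 1.94-fold and 1.90-fold lower. MHC class I genes were lower in 5 of 15 (median -0.55, percentile 0.0), with H2-Q6 at 2.46-fold lower and H2-Q7 at 1.79-fold lower. Interferon-gamma response genes were lower in 4 of 15 (median -0.49, percentile 0.01), among them Cxcl9, a T-cell attractant, at 2.30-fold lower (2.22 to 2.39), Serpina3g at 2.75-fold lower and Gbp2 at 1.78-fold lower. Type I interferon genes were lower in 4 of 27 (median -0.27, percentile 0.0), with Irf7 at 1.83-fold lower and Oas3 at 1.86-fold lower. Ccl5, on the inflammatory list (3 of 8 lower, median -0.19, percentile 5.61), was 4.77-fold lower (4.63 to 4.93). It is also on the cytotoxic list, and RNA or doublets of T and NK cells in the class were not separated from its ratio. The lipid-associated list split, with 2 higher and 2 lower of 12 (median -0.04, percentile 11.46). Gpnmb, a transmembrane glycoprotein, was 5.59-fold lower (5.39 to 5.79) and Spp1, which encodes osteopontin, 3.26-fold higher. The lowest ratio was that of H2-M2, 11.6-fold lower (9.73 to 13.9), followed by Gpnmb, Ly6i at 5.04-fold lower, Ccl5 and Ctsk, the gene of cathepsin K, at 4.69-fold lower.

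In the same macrophage-like cells, p53 response genes had a median log2 ratio of 0.35 (percentile 100), with 2 higher and 1 lower of 11. Cdkn1a, a cell cycle inhibitor induced by p53, was 1.51-fold higher (1.47 to 1.55) and Gdf15 1.54-fold lower. The dissociation stress list was higher in 3 of 15 (median 0.37, percentile 100), including Fosb at 2.05-fold. Hypoxia genes (0 of 15 met the rule, median -0.06) and complement component 1q genes (0 of 3, median 0.16) did not reach the size rule. In all, 112 genes were higher and 194 lower of 2948 measured, and with TMM scaling the split was 158 and 143. Different clusters held the class. Cluster 4, led by Gpnmb and Ctsk, had 48.9% of macrophage-like cells without treatment and 4.66% after radiation, and cluster 9, led by Pf4, Ccl8 and Folr2, had 16.9% and 55.5%. At Leiden resolution 2, Fabp4 turned from 1.68-fold lower to a ratio of 1.04 and Gdf15 to 1.23. Over all kept cells of a library, not this class alone, endothelial marker genes summed to 79.0 CPM without treatment and 20.7 CPM after radiation, and hemoglobin genes to 309.6 and 122.8 CPM.

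Monocyte-like cells had lower interferon genes after radiation. Type I interferon genes were lower in 18 of 27 (median -0.71, percentile 0.0), such as Ifit3 at 2.05-fold lower (1.99 to 2.10), Irf7 at 1.92-fold lower and Usp18 at 1.90-fold lower. Interferon-gamma genes were lower in 12 of 17 (median -0.76, percentile 0.0), with Gbp5 at 2.20-fold lower and Cxcl9 at 1.94-fold lower. Chemokine genes were higher in 8 of 12 (median 1.24, percentile 100), with Cxcl2 at 3.59-fold and Ccl7, a monocyte attractant, at 3.34-fold. Arg1 was 2.91-fold higher (2.76 to 3.07). Cluster 5, led by interferon genes, held 50.6% of monocyte-like cells without treatment and 27.9% after radiation, and cluster 6, led by Thbs1, Cxcl3 and Arg1, 22.6% and 52.3%.

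In CD8 T-like cells of tumor 1, radiation went with higher naive and memory genes and lower checkpoint genes. Naive and memory genes were higher in 6 of 11 (median 1.03, percentile 100), with Tcf7, a transcription factor of memory T cells, at 2.5-fold (1.99 to 3.11) and Lef1 at 2.47-fold. Checkpoint and exhaustion genes were lower in 5 of 12 (median -0.63, percentile 0.0), including Tox, a regulator of exhaustion, at 2.17-fold lower (1.85 to 2.55) and Lag3, an inhibitory receptor, at 1.94-fold lower (1.66 to 2.28). Cdkn1a was 3.52-fold higher (2.80 to 4.43), and 3 of 12 p53 response genes were higher (median 0.31, percentile 99.5). Cytotoxic genes split, with 4 higher and 1 lower of 15 (median -0.05, percentile 31.7), and cell cycle genes were lower in 3 of 18 (median -0.24, percentile 0.16), such as Stmn1 at 1.80-fold lower. Th1 genes had 1 higher and 1 lower of 9 (median 0.20, percentile 97.8; -0.05 with cells of equal weight). Among the lowest ratios were those of Itih5 (3.54-fold lower) and Dhrs7 (2.62-fold lower).

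Gzma, a granzyme, was 5.13-fold higher in these CD8 T-like cells, yet 17.0% of its UMIs lay in 1 cell and the ratio was 0.821 with no doublets removed. Gzmc, at 5.17-fold, had 38.8% in 1 cell. The other top genes were Ccl7 (4.87-fold), Pf4 (4.33-fold) and Cxcl2 (3.70-fold), which in macrophage-like cells stood at 478 and 1944, 1083 and 4623, and 576 and 2619 CPM in the untreated and radiation libraries. There were 946 and 258 CD8 T-like cells with 95 genes higher and 105 lower of 3147, and the number lower was 181 with each cell thinned to 1000 UMIs. Gene levels were summed over the whole class, whose make-up differed. The naive-led sub-cluster 11 held 5.81% of CD8 T-like cells without treatment and 20.2% after radiation, sub-cluster 4, with Cxcr6, Tox and Lag3 among its top 10 genes, 47.6% and 21.3%, and sub-cluster 13, led by Gramd3 and Gimap6, 8.77% and 29.5%. The list differences are therefore not shown to be changes within cells of 1 type. Without sub-cluster 11, checkpoint genes had a median of -0.45 (4 of 13 lower) and naive genes 1.14 (3 of 10 higher).

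NK-like cells after radiation had higher cell cycle genes, with 8 of 17 higher (median 1.10, percentile 100), including Ube2c, a mitotic ubiquitin conjugase, at 25.4 against 145 CPM (5.70-fold, 3.85 to 8.78), Birc5, the gene of survivin, at 3.02-fold (2.19 to 4.27) and Pclaf at 2.47-fold. Th1 genes were lower in 2 of 8 (median -0.56, percentile 0.42), Il12rb2 and Stat4, which carry the interleukin-12 signal, at 1.95-fold and 1.83-fold lower. Cytotoxic genes split, with Gzmf at 6.78-fold higher on 23 UMIs in the untreated library and Ccl5 at 2.33-fold lower (2 higher, 3 lower of 16, median -0.10, percentile 4.38; 0.04 with TMM factors), and naive genes were lower in 3 of 8 (median -0.56, percentile 0.54). Sub-cluster 9, with granzyme genes such as Gzmc and Gzmf at the top and a median of 13408 UMIs, held 6.16% of NK-like cells without treatment and 15.7% after radiation, so these are differences of the class as a whole. The cell cycle list was also higher in Treg-like cells, in 17 of 18 members (median 1.39, percentile 100), where the cycling sub-cluster 3 held 7.06% of the class without treatment and 38.1% after radiation. Cytotoxic genes were lower there in 6 of 12 and higher in 1 (median -1.14, percentile 0.0) and stress genes lower in 7 of 15 (median -0.70, percentile 0.36). Checkpoint genes were lower in 7 of 9 (percentile 0.18) and Treg effector genes in 5 of 14 (percentile 2.79). In this class 746 genes were higher and 1018 lower of 3808, and median UMIs per cell were 1151 without treatment and 1873 after radiation. Neutrophil activation genes were higher in 4 of 12 in neutrophil-like cells (median 0.48, percentile 100).

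The combination was then compared with no treatment in tumor 1, with the same single untreated library as in the comparison above. Any oddity of that library would enter both, so shared directions are not separate evidence. CD8 T-like cells were 2.95-fold lower (3.36% against 9.90%; ratio interval 0.293 to 0.393), CD4 T-like cells 3.64-fold lower (0.159 to 0.475) and Treg-like cells 6.14-fold lower (0.579% against 3.56%; 0.116 to 0.229). NK-like cells were 2.74-fold higher (2.39 to 3.15), neutrophil-like cells 2.37-fold (1.97 to 2.85) and macrophage-like cells 1.18-fold (1.13 to 1.24). B-like cells were 2.93-fold lower (14 cells in the combination library; 0.192 to 0.609), although without clustering the ratio was 0.872. The monocyte-like ratio was 0.931 (0.882 to 0.983) and turned to 1.25 with 4000 variable genes, where the macrophage-like ratio was 1.83. The macrophage-like ratio was 2.74 with stricter cell filters and 2.5 with no filter on cells, and the neutrophil-like ratio was 1.38 from marker UMIs.

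In macrophage-like cells, MHC class II genes were lower in 6 of 7 members (median -1.15, percentile 0.0), with H2-Aa at 2.83-fold lower (2.78 to 2.88), H2-Eb1 at 2.73-fold lower and Cd74, the class II invariant chain, at 2.22-fold lower. MHC class I genes were lower in 7 of 15 (median -0.56, percentile 0.0), including H2-D1 at 1.87-fold lower. Chemokine genes were higher in 9 of 12 and lower in 1 (median 1.98, percentile 100), with Cxcl1 at 13.8-fold, Cxcl3 at 9.27-fold and Cxcl2 at 7.19-fold. Alternatively activated genes were higher in 5 of 9 (median 1.76, percentile 100), with Arg1 at 7.66-fold (7.22 to 8.13) and Folr2 at 3.71-fold. Ccl24, an eosinophil attractant, was 9.52-fold higher with 31.6% of its UMIs in 1 cell of the combination library. Type I interferon genes were lower in 6 of 27 (median -0.23, percentile 0.5), with Irf7 at 2.30-fold lower, and interferon-gamma genes in 4 of 15 (median -0.17, percentile 9.98), with Cxcl9 at 2.18-fold lower. The dissociation stress list was higher in 9 of 15 (median 0.79, percentile 100), with Fosb at 3.04-fold, Zfp36 at 2.35-fold and Dusp1 at 2.29-fold, and p53 genes in 4 of 11 (median 0.49, percentile 99.9), with Mdm2, the p53 inhibitor, at 1.93-fold. Lipid-associated genes had 3 higher and 5 lower of 12 (median -0.34, percentile 0.53) and inflammatory genes 1 higher and 3 lower of 8 (median -0.32, percentile 2.29). The extremes were Areg at 14.4-fold higher and H2-M2, Cadm1 and Ccl5 at 11.49-fold, 6.20-fold and 5.34-fold lower. For Ccl5, RNA or doublets of T and NK cells were again not separated. In all, 240 genes were higher and 247 lower of 3027, or 294 and 195 with TMM scaling. Cluster 4 held 48.9% and 2.96% of the class and cluster 9 16.9% and 64.4%. Over all kept cells of these libraries hemoglobin genes summed to 309.6 and 0.4 CPM, and endothelial marker genes to 79.0 and 17.5 CPM.

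Monocyte-like cells of the combination library had lower type I interferon genes in 18 of 27 (median -0.71, percentile 0.0), with Ifit3 at 3.19-fold lower (3.08 to 3.29) and Isg20 at 2.58-fold lower. Hypoxia genes were higher in 8 of 15 (median 0.64, percentile 100), such as Ndrg1 at 1.94-fold and Pgk1, a glycolytic enzyme, at 1.84-fold. Cluster 5, led by interferon genes, held 50.6% of the class without treatment and 24.8% with the combination, and cluster 6 22.6% and 55.3%. In CD8 T-like cells, checkpoint genes were lower in 8 of 13 (median -0.67, percentile 0.0), with Tox at 2.73-fold lower, Lag3 at 2.5-fold lower and Havcr2, which encodes TIM-3, at 1.79-fold lower. Cytotoxic genes were lower in 6 of 15 and higher in 2 (median -0.32, percentile 0.2), with Prf1, the pore-forming perforin, at 2.68-fold lower (2.32 to 3.12). Naive and memory genes were higher in 7 of 11 (median 1.18, percentile 100), with Tcf7 at 2.64-fold, and p53 genes in 4 of 12 (median 0.43, percentile 99.9), with Cdkn1a at 4.00-fold (22% of UMIs in 1 cell). The cell cycle median was 0.23 (1 of 18 higher, percentile 98.5), which turned to -0.25 with cells of equal weight. Cxcr4, a chemokine receptor, was 4.33-fold higher, Ifitm1 5.46-fold with 43.5% of its UMIs in 1 cell, Nrn1 6.47-fold lower on 11 UMIs in the combination library, and Ccl1 5.13-fold lower with 40.7% of the untreated UMIs in 1 cell. In NK-like cells the cell cycle list was higher in 11 of 18 (median 1.19, percentile 100), with Pclaf at 3.64-fold (2.94 to 4.56). Cytotoxic genes had 1 higher and 4 lower of 16 there (median -0.37, percentile 0.1; 0.001 with cells of equal weight), Th1 genes 3 lower of 8 (median -0.70, percentile 0.03), and sub-cluster 9 held 6.16% of NK-like cells without treatment and 16.9% with the combination. The CD8 T-like comparison had 219 genes higher and 240 lower of 3186 between 946 and 209 cells. Sub-cluster 4 held 47.6% of these cells without treatment and 21.1% with the combination, sub-cluster 13 8.77% and 28.2% and the naive-led sub-cluster 11 5.81% and 14.8%, so these list differences too are not shown to lie within cells of 1 type.

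With anti-CTLA4 added to radiation in tumor 1, most shares lay close to those of radiation alone and that of Treg-like cells was lower. Treg-like cells made up 0.579% with the antibody (36 cells) and 1.74% without it (155 cells), 3.0-fold lower (ratio 0.333, 0.232 to 0.478). CD8 T-like cells were at 3.36% and 2.89% (ratio 1.16, 0.971 to 1.39), NK-like cells at 8.38% and 8.35% (ratio 1.00, 0.901 to 1.12) and macrophage-like cells at 35.9% and 35.6% (ratio 1.01, 0.965 to 1.052), all with intervals that include 1. CD8 T-like cells per Treg-like cell were 5.81 (4.06 to 8.52) with the antibody and 1.66 (1.36 to 2.04) without it. B-like cells (ratio 0.456, 0.25 to 0.832, 14 and 44 cells) and neutrophil-like cells (ratio 0.835, 0.722 to 0.965) were lower. Without clustering the ratios were 0.825, with an interval that included 1, and 1.07. The macrophage-like ratio was 0.804 (0.744 to 0.868) at Leiden resolution 2 and 0.894 (0.847 to 0.944) without clustering. The CD8 T-like ratio was 1.64 (1.23 to 2.19) with stricter cell filters and 1.45 (1.23 to 1.71) when the myeloid-marker T and NK sub-clusters were kept. Among these, sub-cluster 15 held 0.981% of cells in the combination library of tumor 1 and 0.101% in the radiation library (61 and 9 cells). It counted there as CD8 T-like, with 5 markers of that class but 0 of them among its 10 leading genes. Sub-clusters 12 and 13, named CD8 T-like throughout, had the same 5 and 0. The leading genes of sub-cluster 15 were Penk, Tnfrsf4, Ctla4, Top2a, Stmn1, histone genes and Ppbp, which also leads the macrophage-like cluster 9. Its cells were left out of the Treg-like share above, and whether they belong in it was not tested.

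Few macrophage genes differed between these libraries, with 33 higher and 1 lower of 2882, and at Leiden resolution 2 the number higher was 9. With each cell thinned to 1000 UMIs the counts were 75 and 19. Ccl24 was highest at 3.27-fold (2.92 to 3.66; 31.6% of UMIs in 1 cell), followed by Egr2, an immediate early transcription factor, at 2.19-fold (2.01 to 2.38), Tnfaip3, an inhibitor of NF-kappaB, at 1.83-fold, Mmp19 at 1.77-fold and Chka at 1.73-fold. Arg1 rose from 305 to 496 CPM, 1.63-fold (1.58 to 1.68), and Cxcl2 1.58-fold. The gene that was lower was Ckb, a creatine kinase, at 1.70-fold lower. No MHC class II gene met the size rule, while the median of the 7 was -0.41 (percentile 0.0), and interferon-gamma genes had a median of 0.22 (0 of 15 met the rule, percentile 99.8). The dissociation stress list was higher in 4 of 15 (median 0.29, percentile 100), with Hspa1b, a heat shock gene, at 1.65-fold and Dusp1 at 1.63-fold. Alternatively activated genes were higher in 2 of 9 (median 0.32, percentile 99.8) and chemokine genes in 1 of 12 (median 0.19, percentile 99.9), and complement component 1q genes had a median of -0.41 (0 of 3 met the rule, percentile 0.26). Type I interferon (median 0.03, percentile 70.1) and MHC class I genes (median -0.03, percentile 39.6) moved little. Cluster 9 held 55.5% of the class with radiation and 64.4% with the combination, and cluster 8 39.9% and 32.7%. In monocyte-like cells Ifit3 was 1.56-fold lower and Cxcl1 4.47-fold lower (3.88 to 5.18), and Ccl24 was 2.47-fold higher.

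In CD8 T-like cells of tumor 1, the combination library had lower cytotoxic genes than radiation alone, in 6 of 15 with 1 higher (median -0.34, percentile 0.0). Prf1 was 2.06-fold lower (1.73 to 2.45). Ccl3 and Ccl4, chemokines of effector T cells, were 3.81-fold and 2.64-fold lower with 23.8% and 18.8% of their UMIs in 1 cell of the radiation library, and Gzmc was 2.27-fold lower with 38.8% in 1 cell. Cell cycle genes were higher in 6 of 18 (median 0.48, percentile 100), including Nusap1 at 2.19-fold (21.9% in 1 cell), Birc5 at 2.14-fold, Pclaf at 1.85-fold and Top2a, a topoisomerase, at 1.80-fold (1.5 to 2.17). Checkpoint genes (0 of 12, median -0.10) and naive genes (0 of 11, median 0.08) did not meet the rule, and Th1 genes had 1 higher and 2 lower of 9 (median -0.24, percentile 1.39). Bhlhe40, a regulator of cytokine genes, was 1.58-fold higher and Cxcr6, a tissue homing receptor, 1.51-fold lower. The extremes were Ifitm1 at 13.8-fold higher (43.5% in 1 cell), Serpinb9b at 7.16-fold higher (90.0% in 1 cell), Nup88 at 2.40-fold higher and Ccl1 at 15.8-fold lower (63.1% in 1 cell). With 209 and 258 cells, 117 genes were higher and 86 lower of 3159, and the number lower was 140 with no doublets removed. Slc17a6, 2.72-fold lower, had a ratio of 1.03 with cells thinned to 1000 UMIs, and Nfkbid, 2.34-fold higher, a ratio of 0.631. In NK-like cells Gzmf was 3.10-fold higher (39.9% in 1 cell) and Gzmd 1.77-fold lower.

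Adding anti-CTLA4 in tumor 2 went with a larger CD8 T-like share. CD8 T-like cells made up 29.3% of CD45-sorted cells in the combination library and 14.1% in the radiation library, 2.07-fold higher (1.96 to 2.19). Treg-like cells were 1.36-fold lower (3.57% against 4.86%; ratio 0.735, 0.641 to 0.843), so CD8 T-like cells per Treg-like cell were 8.19 (7.26 to 9.26) against 2.91 (2.64 to 3.20). B-like cells were 2.74-fold lower (3.46% against 9.46%; ratio interval 0.322 to 0.415) and T sub-clusters led by naive genes fell from 17.7% to 2.36%. NK-like cells (ratio 0.746, 0.608 to 0.916), neutrophil-like cells (0.678, 0.487 to 0.943) and monocyte-like cells (0.896, 0.846 to 0.948) were lower, and macrophage-like cells were at 16.3% and 15.8% (ratio 1.03, 0.969 to 1.10). CD4 T-like cells were 3.11-fold lower (3.003% against 9.33%; ratio interval 0.282 to 0.368), but without B-like and naive-led cells in either library the ratio turned to 2.63, and with stricter cell filters to 5.52. The CD8 T-like ratio without those cells was 2.71 (2.53 to 2.90), and with those stricter filters it was 4.13. The macrophage-like ratio without those cells was 0.799 (17.4% against 21.7%; 0.751 to 0.851), and it was 1.23 (1.14 to 1.32) from marker UMIs, so its direction was not settled. Without naive-led cells, CD8 T-like cells per Treg-like cell were 7.93 against 1.67. The radiation library of tumor 2 also held 2.87% of T cells of mixed CD4 and CD8 markers against 0.369%.

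Macrophage-like cells of tumor 2 had more interferon-gamma response and MHC class II RNA with the antibody. Interferon-gamma genes were higher in 8 of 17 and lower in 0 (median 0.70, percentile 100). Cxcl9 rose from 280 to 971 CPM, 3.46-fold (3.33 to 3.60), and Iigp1, Gbp2 and Gbp4, interferon-induced GTPases, were 2.12-fold (1.96 to 2.31), 2.00-fold (1.88 to 2.13) and 1.99-fold (1.82 to 2.18) higher. MHC class II genes were higher in 3 of 8 (median 0.58, percentile 100), among them H2-Ab1 at 1.61-fold (1.59 to 1.64) and H2-Eb1 at 1.59-fold. Type I interferon genes were lower in 2 of 27, Isg20 and Irf7, the latter at 916 against 598 CPM, with a median of -0.28 (percentile 0.0). Inflammatory genes were higher in 2 of 8 (median 0.23, percentile 100), with Ptgs2, the gene of cyclooxygenase 2, at 1.70-fold. Lipid-associated genes had 1 higher and 1 lower of 12 (median -0.26, percentile 0.01), Gpnmb at 1.90-fold lower (1.81 to 1.99) and Cd36, a fatty acid transporter, at 1.57-fold higher. Other extremes were Selm at 1.95-fold higher, Slpi at 2.92-fold lower (33.9% of UMIs in 1 cell), Ly6c2, a monocyte marker, at 1.97-fold lower (1.91 to 2.03), Syngr1 at 1.83-fold lower and Kdr, an endothelial gene, at 1.71-fold lower. Endothelial markers over all kept cells went from 48.4 to 27.9 CPM, a sum that includes Kdr itself and so is not a separate measure for it. The stress list (median 0.09, percentile 98.4), alternatively activated genes (0.12, 97.99) and the 4 cell cycle genes measured (0.56, 99.98) lay high among random lists with 0 members that met the rule. MHC class I (-0.06), chemokine (-0.02), hypoxia (-0.01) and p53 (-0.02) lists lay between percentiles 19.5 and 48.4, also with 0 members. In all, 22 genes were higher and 10 lower of 2940, or 51 and 47 with each cell thinned to 1000 UMIs. T-cell signal in these macrophage-like cells was also higher, with Pdcd1 at 3.39 and 11.76 CPM and 0.702% and 2.19% of the cells positive by the CD8 marker gate, and T-cell RNA or doublets in the class were not separated from these differences. Cluster 4 held 24.3% of the class with radiation and 12.4% with the combination, and cluster 8, led by C1qa and C1qc, 50.9% and 58.1%.

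**Figure D2:**
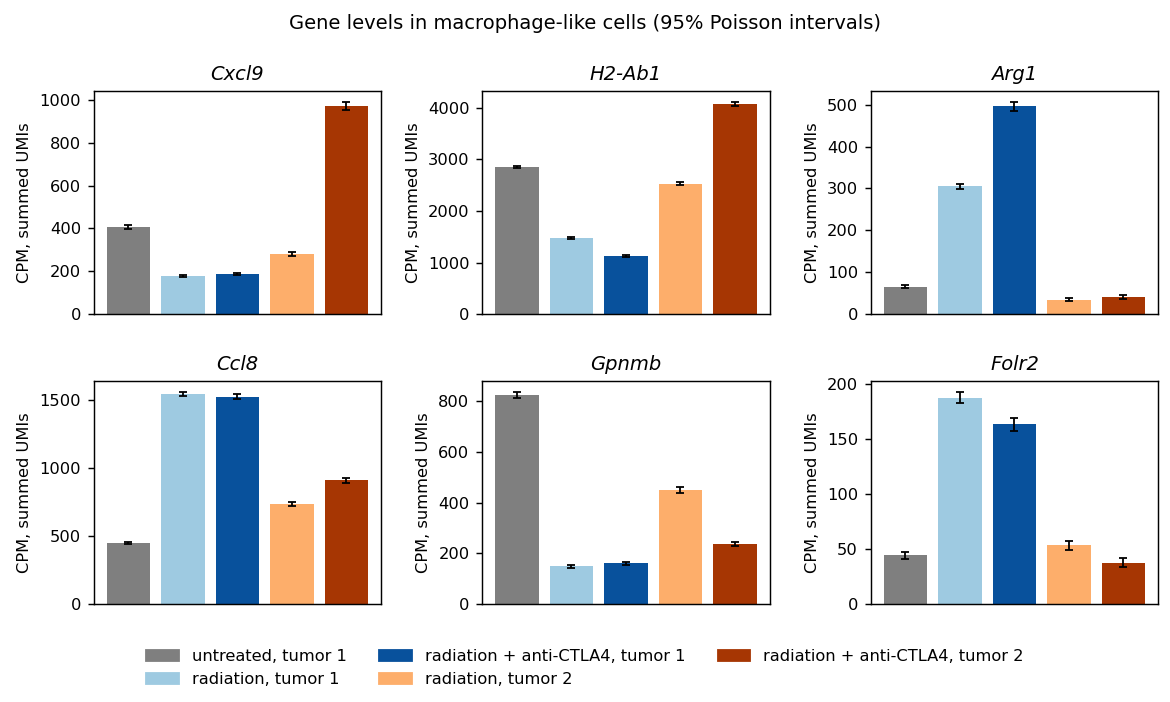
Bars show CPM of summed UMIs in macrophage-like cells of each pooled library for 6 genes, with 95% Poisson intervals that cover counting error only. Cxcl9 and H2-Ab1 are lower in both treated libraries of tumor 1 than in the untreated one and higher in the combination library of tumor 2 (971 CPM for Cxcl9) than in the radiation library of tumor 2 (280 CPM).

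Monocyte-like cells of tumor 2 showed the same direction for interferon-gamma genes, with 6 of 17 higher (median 0.45, percentile 100), Cxcl9 at 2.98-fold (2.87 to 3.09) and Serpina3g at 1.72-fold. Complement component 1q genes were higher in 2 of 3 (median 0.61, percentile 100), C1qa at 1.60-fold (1.53 to 1.67) and C1qc at 1.53-fold. Ccl8 was 2.48-fold higher and Ptgs2 2.22-fold higher, and Cxcl3 was 1.82-fold lower.

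CD8 T-like cells of tumor 2 had far lower naive genes with the antibody, in 8 of 11 with 1 higher (median -2.08, percentile 0.0). S1pr1, the receptor for exit from lymph nodes, was 8.51-fold lower (7.28 to 9.99), Tcf7 8.28-fold lower (7.38 to 9.32) and Lef1 8.03-fold lower. Igfbp4, Klf3 and Pik3ip1 were 27.3-fold, 10.9-fold and 8.33-fold lower. Cytotoxic genes were higher in 4 of 17 (median 0.38, percentile 100), with Gzmc at 3.09-fold (2.71 to 3.54), Gzmf at 2.82-fold (2.62 to 3.03) and Gzme at 3.35-fold (53.4% of UMIs in 1 cell of the radiation library). Pdcd1, which encodes the checkpoint receptor PD-1, was 1.98-fold higher (221 against 437 CPM, 1.88 to 2.09) and Cd160 1.57-fold higher, the 2 of 11 checkpoint genes that met the rule (median 0.44, percentile 100). Cell cycle genes were higher in 10 of 18 (median 0.65, percentile 100), including Ccnb2, a mitotic cyclin, at 1.86-fold and Ube2c at 1.79-fold. Rora was 3.22-fold higher (2.91 to 3.56), Ccl1 4.49-fold (3.61 to 5.65), Tff1 3.58-fold and Bhlhe40, on the Th1 list (1 of 9 higher, median 0.44, percentile 99.9), 1.73-fold. The stress list was lower in 3 of 15 (median -0.09, percentile 3.52), with Fos at 2.26-fold lower, and p53 genes split (1 higher and 1 lower of 9, median 0.01).

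The naive-led sub-cluster 11 held 42.7% of CD8 T-like cells in the radiation library of tumor 2 and 3.18% in the combination library, and median UMIs per CD8 T-like cell were 2958 and 6381.5. Sub-cluster 4 held 22.96% and 40.4% of these cells and sub-cluster 5, led by Rgs16, Gzmf and Pdcd1, 11.8% and 27.1%. In the whole class 108 genes were higher and 140 lower of 3001, and without that sub-cluster the counts were 19 and 47, with 0 of 18 cell cycle genes and 0 of 11 checkpoint genes meeting the rule. The medians without it were -0.06 for cytotoxic genes (3 of 17 higher), -0.02 for checkpoint genes, 0.18 for cell cycle genes and -1.32 for naive genes. Without it Gzmc was 2.94-fold, Gzmf 2.03-fold and Rora 2.47-fold higher, the Pdcd1 ratio was 1.42, and Tcf7 and Lef1 were 3.48-fold and 2.5-fold lower. Igfbp4, Klf3, S1pr1 and Pik3ip1 were then 7.63-fold, 6.94-fold, 3.51-fold and 2.29-fold lower, and the ratios of Ccnb2, Bhlhe40 and Cd160 were 1.34, 1.26 and 1.18, below the size rule. The number of genes higher was 232 with cells of equal weight and 293 with each cell thinned to 1000 UMIs.

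In NK-like cells of tumor 2, with 138 and 258 cells, cell cycle genes were higher in 7 of 16 with the antibody (median 0.73, percentile 100), including Rrm2, a ribonucleotide reductase subunit, at 4.91-fold (2.61 to 9.89; 13 and 47 UMIs) and Pclaf at 3.33-fold (2.45 to 4.57). Gzmc was 2.21-fold higher and Gzmd 3.12-fold lower (59.5% of UMIs in 1 cell). Sub-cluster 9 held 5.43% of NK-like cells with radiation and 8.70% with the combination. In Treg-like cells, cell cycle genes were higher in 15 of 18 (median 1.14, percentile 100), and the cycling sub-cluster 3 held 8.08% and 27.7% of the class. Most other lists were lower in these cells, with stress genes in 10 of 15 (median -0.78, percentile 0.0), Treg effector genes in 8 of 14 (median -0.68, percentile 0.0), naive genes in 5 of 10 (median -0.86, percentile 0.0) and cytotoxic genes in 4 of 12 (median -0.55, percentile 0.16). Treg effector genes had a median of 0.35 in CD8 T-like cells (0 of 9 met the rule, percentile 99.1), which was -0.04 without the naive-led sub-cluster.

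The antibody target and its partners were read in each library. Ctla4 in Treg-like cells was 1283 CPM (1194 to 1377) untreated, 1046 (972 to 1125) and 1153 (979 to 1349) in tumor 1 with radiation and the combination, and 1258 (1196 to 1323) and 718 (676 to 762) in tumor 2. It was 1.75-fold lower with the antibody in tumor 2 (1.62 to 1.90), where the make-up and depth of the class differed, with median UMIs of 1449 and 2529 per cell, and Ctla4 UMIs per cell were 2.68 with radiation and 3.63 with the combination. The lower CPM is therefore not a lower count of Ctla4 UMIs per cell. In CD8 T-like cells Ctla4 was between 80.7 and 122 CPM in the 5 libraries, and the ratio in tumor 2 was 1.46 (1.34 to 1.60), below the size rule. Pdcd1 in CD8 T-like cells was 309 CPM untreated, 248 and 200 in tumor 1, and 221 and 437 in tumor 2. Cd274, the gene of PD-L1, was between 176 and 251 CPM in macrophage-like cells without a call and rose in neutrophil-like cells of tumor 1 from 618 CPM untreated to 1029 CPM with radiation (1.67-fold, 1.44 to 1.94) and 1265 CPM with the combination (2.05-fold). Cd86 in macrophage-like cells was between 113 and 134 CPM and Cd80 between 14.7 and 21.9 CPM.

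**Figure D3:**
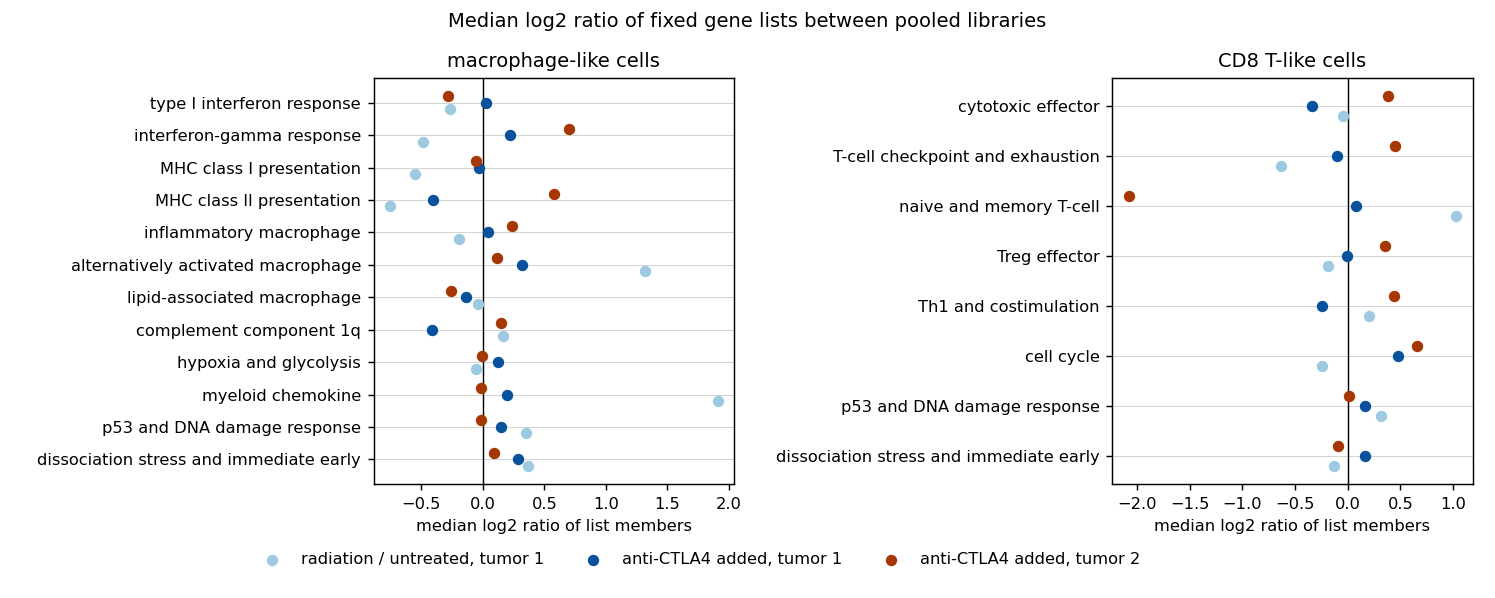
Points show the median log2 ratio of each fixed gene list in macrophage-like and CD8 T-like cells for radiation over untreated in tumor 1 and for the combination over radiation in tumors 1 and 2. MHC class II genes in macrophage-like cells have medians of -0.76, -0.41 and 0.58, and naive genes in CD8 T-like cells 1.03, 0.08 and -2.08, in that order.

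The effect of adding anti-CTLA4 was set side by side for the tumors, which share no library. In CD8 T-like cells, 40 of 2849 genes measured in both tumors met the rule in both, and 32 of them had the same sign. Of these 19 were higher in both, against 2.51 if the calls were independent, and 13 lower, against 2.94, and across genes, which are not replicates, the correlation of log2 ratios was 0.129 with a covariance of 0.0152. The expected counts take every gene as equally likely to be called, so an excess over them does not show a shared effect. The naive-led sub-cluster held a smaller part of the class with the antibody in both tumors, so shared genes may also carry that make-up. At a ratio of 2 the sign was shared by 3 of 5 genes (60.0%, interval 14.7 to 94.7). In macrophage-like cells 2 of 2 genes shared the sign (correlation 0.304), in monocyte-like cells 3 of 3, in NK-like cells 7 of 7 and in neutrophil-like cells 27 of 34 (79.4%, correlation 0.164). The neutrophil-like count rested on 107 and 52 cells in the radiation and combination libraries of tumor 2. With TMM factors the monocyte-like count was 2 of 3, and at a ratio of 2 the neutrophil-like count was 2 of 3. The tumors of a treatment may come from the same mice, so tumor 2 is not an independent repeat of tumor 1.

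Tumors 1 and 2 of the same treatment were also compared. Each library used here and in the next comparison also entered comparisons above. Any oddity of it would enter both, so genes that mirror those results are not separate evidence. After radiation alone, CD8 T-like cells were 4.89-fold higher in tumor 2 than in tumor 1 (4.30 to 5.56; 8.08 with no doublets removed, 7.04 from marker UMIs and 6.22 with stricter cell filters). The radiation libraries held 9.46% and 0.493% B-like cells, 2.20% and 8.35% NK-like cells and 15.8% and 35.6% macrophage-like cells in tumors 2 and 1. In macrophage-like cells of tumor 2, Arg1 was 8.77-fold lower (7.97 to 9.68), Cxcl3 8.22-fold, Cxcl1 7.60-fold and Areg 6.51-fold lower, chemokine genes were lower in 9 of 12 (median -1.32, percentile 0.0) and MHC class II genes higher in 5 of 8 (median 0.77, percentile 100). Cd81 was 4.22-fold, Ccl5 3.82-fold and Kdr 3.60-fold higher, and endothelial markers over all kept cells were at 20.7 CPM in tumor 1 and 48.4 CPM in tumor 2. The endothelial sum includes Kdr itself and the UMIs of macrophage-like cells, so it is not a separate measure for Kdr. RNA or doublets of T and NK cells were not separated from the Ccl5 ratio. Cluster 9, led by Pf4, Ccl8 and Folr2, held 55.5% of macrophage-like cells in tumor 1 and 24.8% in tumor 2, and cluster 4 4.66% and 24.3%, so these ratios also carry the make-up of the class. Naive genes in CD8 T-like cells had a median of 0.53 (5 of 11 higher) that turned to -0.38 without the naive-led sub-cluster, and Gzmc and Gzma were 10.2-fold and 9.01-fold lower, with 38.8% and 17.0% of the UMIs of tumor 1 in 1 cell. Sub-cluster 11 held 20.2% of CD8 T-like cells in tumor 1 and 42.7% in tumor 2, and sub-cluster 13 29.5% and 7.01%.

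With the combination, CD8 T-like cells were 8.71-fold higher in tumor 2 than in tumor 1 (7.59 to 9.99; 15.6 with stricter cell filters and 6.76 with myeloid-marker sub-clusters kept). In macrophage-like cells Cxcl9 was 5.20-fold higher in tumor 2 (5.0 to 5.41), Dnase1l3 20.8-fold higher (16.2 to 27.2) and Cadm1 8.07-fold higher, and Cxcl3 was 23.3-fold, Arg1 12.2-fold and Pf4 6.91-fold lower. MHC class II genes were higher in 6 of 8 (median 1.75, percentile 100), interferon-gamma genes in 8 of 17 (median 0.67, percentile 100) and chemokine genes lower in 10 of 12 (median -1.51, percentile 0.0). Cluster 9 held 64.4% of the class in tumor 1 and 29.5% in tumor 2 and cluster 4 2.96% and 12.4%. Over all kept cells of these libraries hemoglobin genes summed to 0.4 and 483.9 CPM. Cd3g, a T-cell gene, was 9.84-fold higher in these macrophage-like cells and Gzma, a gene of NK and T cells, 14.9-fold lower. In CD8 T-like cells naive genes were lower in 7 of 11 (median -1.79, percentile 0.0) and checkpoint genes higher in 4 of 12 (median 0.45, percentile 100). Sub-cluster 13 held 28.2% of CD8 T-like cells in tumor 1 and 2.57% in tumor 2 and the naive-led sub-cluster 11 14.8% and 3.18%, and without the latter the checkpoint median was 0.28. Klra7, an NK receptor gene, was 12.7-fold lower and Nrn1 5.78-fold higher, on 11 UMIs in tumor 1. The tumor 2 libraries were not compared with the untreated one, which is of tumor 1.

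Positions of genes named often, on GRCm38, were as follows. Ctla4 lies on chromosome 1 at 60887000 to 60915832, Pdcd1 on chromosome 1 at 94038305 to 94052553 and Cxcl9 on chromosome 5 at 92321347 to 92328079. Areg lies on chromosome 5 at 91139599 to 91148432, Ccl24 on chromosome 5 at 135569937 to 135573049 and Gpnmb on chromosome 6 at 49036546 to 49070929. Arg1 lies on chromosome 10 at 24915221 to 24927484, Igfbp4 on chromosome 11 at 99041244 to 99054392 and H2-Ab1 on chromosome 17 at 34257689 to 34269419, and all are annotated as protein coding.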

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

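The tests on B-like and naive-led cells and on the CD8 T-like share were chosen only after the results were seen, and those on macrophage-like gene levels were written after cluster sizes had been seen but before their own values were computed. Several differences went opposite ways with anti-CTLA4 in the tumors. The share of all T cells had a ratio of 0.85 in tumor 1 and 1.16 in tumor 2, macrophage-like and monocyte-like cells together 1.03 and 0.955, and the unnamed hemoglobin-led cluster 0.563 and 3.53. The MHC class II median in macrophage-like cells was -0.41 in tumor 1 and 0.58 in tumor 2, the cytotoxic median in CD8 T-like cells -0.34 and 0.38, and the Th1 median -0.24 and 0.44. Without the naive-led sub-cluster the cytotoxic medians were -0.29 and -0.06, no longer opposite, and the Th1 medians -0.315 and 0.11 (0 of 9 genes of tumor 2 met the size rule). The contrast of all T cells also depends on which cells are counted, as the ratio of tumor 1 was 1.025 (0.893 to 1.18) with myeloid-marker sub-clusters kept. The causes of these differences between tumors were not tested. The hemoglobin-led cluster, which held 5.52% of cells in the combination library of tumor 2, was not analysed further. Barcodes left out for mitochondrial UMIs made up 8.28%, 14.75%, 10.04% and 15.98% of the radiation and combination libraries of tumor 1 and then of tumor 2, against 5.72% in the untreated library, and why they differ was not tested.

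B-like cells and naive-led T cells were far more frequent in the radiation library of tumor 2 than in that of tumor 1. If lymphoid tissue had been pooled with those tumors, B-like cells and both the CD4-like and CD8-like naive sub-clusters should all be enriched, and the smallest of the 3 ratios was 10.4. Lymphocytes that gathered inside the tumors may give the same numbers, so these cannot be told apart without tissue sections or records of the dissection. Blood left in the tumors would bring neutrophil-like cells, whose ratio to tumor 1 was 0.171 but to the combination library of tumor 2 was 1.48 (1.06 to 2.05), which leaves blood open too. Erythroid markers (hemoglobin genes and Alas2) over all kept cells also went both ways. They were at 427.3 CPM in this library, 122.8 CPM in the radiation library of tumor 1 and 483.9 CPM in the combination library of tumor 2.

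The larger CD8 T-like share in tumor 2 with anti-CTLA4 was weighed against dilution by those cells. Without B-like and naive-led cells in either library the ratio of shares was 2.71 (2.53 to 2.90). This also took out naive-led CD8 T-like cells, leaving 948 of 1655 in the radiation library and 2378 of 2456 in the combination library. The ratio therefore covers only the other CD8 T-like cells, for which dilution is not the whole account. How much of the difference in the whole class comes from dilution was not separated. With each cell thinned to 1000 UMIs and CD8 T cells taken by marker UMIs, the ratio was 2.25 (2.10 to 2.41). More UMIs per cell therefore do not account for the larger share. The difference may be a biological one, as a hypothesis, but it is between single pooled libraries of 8 tumors and the spread between mice was not measured.

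The macrophage-like gene differences after radiation in tumor 1 were weighed against technical causes. Among the 1004 and 1015 cells with 4000 to 8000 UMIs in the untreated and radiation libraries, 91.5% of the genes (280 of 306) kept a ratio of 1.5 in the same direction. UMIs per cell therefore do not account for most of these genes. The stress list, which handling would raise, had a median of 0.37 (percentile 100), and 5 other lists had medians larger in size, 2 of them higher and 3 lower. That order would go against handling stress as the leading cause only if handling raised no other list more than the stress list. Whether it does was not tested, so the order cannot decide this and handling stays open. Among cells with at most 5% mitochondrial UMIs 99.3% of the genes (304 of 306) kept the ratio, but that limit left 2612 of 2897 and 2716 of 3176 cells in place. It compared nearly the same cells again, so RNA quality stays open, and a cause in the biology cannot be told apart from it. This reading of that test was made after its value was seen. Batch effects between single libraries were not tested.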

How the results depend on the processing

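Shares without B-like and naive-led cells, shares with myeloid-marker sub-clusters kept, and CD8 T-like genes and lists without the naive-led sub-cluster are tests chosen only after the results were seen, and the other settings were fixed beforehand. Main share ratios were those of the treatment comparisons whose interval excluded 1, and all CD8 T-like ones. Of 258 reruns of these 29 ratios, 249 kept their direction. The reruns used the same libraries and leave out most ratios near 1, so they are no measure of ratios in general. Of all values under other settings, 2576 gene ratios were the same, 1538 moved and 15 reversed, 623 list medians were the same, 311 moved and 14 reversed, 317 share ratios were the same, 99 moved and 10 reversed, and 273 counts were the same and 215 moved. Of the agreement values 7 were the same and 1 moved. In what follows U is the untreated library, R is radiation and C the combination, with the tumor number after the letter. Main share ratios and counts that moved are given, with all else that changed direction after an interval that excluded 1, a call by the size rule or a list call. Macrophage-like share ratios of C1/R1 and C2/R2, whose intervals included 1, are given where they turned with an interval that did not. With no doublets removed, share ratios were CD8 T-like 0.180 (R1/U), 0.218 (C1/U), 2.31 (C2/R2), 8.08 (R2/R1), 15.4 (C2/C1), macrophage-like 1.56 (R1/U), 1.60 (C1/U) and monocyte-like 1.01 (R1/U), 1.07 (C1/U). There the gene counts were 3 (C1/R1) lower in macrophage-like cells and 140 (C1/R1) lower in CD8 T-like cells. There the gene ratios turned to 0.821 (R1/U) for Gzma in CD8 T-like cells, 1.18 (C1/U) for Hspb1 in monocyte-like cells and 1.17 (C2/C1) for Ikzf2 in CD8 T-like cells. With at least 500 genes and at most 10% mitochondrial UMIs, share ratios were CD8 T-like 0.143 (R1/U), 0.235 (C1/U), 1.64 (C1/R1), 4.13 (C2/R2), 6.22 (R2/R1), 15.6 (C2/C1), macrophage-like 2.64 (R1/U), 2.74 (C1/U), monocyte-like 0.926 (R1/U) and CD4 T-like 5.52 (C2/R2). With classes from marker UMIs, share ratios were CD8 T-like 0.222 (R1/U), 0.248 (C1/U), 7.04 (R2/R1), 13.004 (C2/C1), Treg-like 0.772 (R1/U), 0.214 (C1/R1), neutrophil-like 1.29 (R1/U), 1.38 (C1/U), 1.07 (C1/R1), macrophage-like 1.38 (R1/U), 0.894 (C1/R1), B-like 0.872 (C1/U), CD4 T-like 0.487 (C2/R2) and monocyte-like 0.801 (C2/R2). Without B-like and naive-led cells, share ratios were CD8 T-like 0.246 (R1/U), 2.71 (C2/R2), 10.4 (C2/C1), Treg-like 0.569 (C2/R2), CD4 T-like 2.63 (C2/R2), NK-like 0.577 (C2/R2), macrophage-like 0.799 (C2/R2) and monocyte-like 0.693 (C2/R2), 1.204 (R2/R1). With no filter on cells, share ratios were Treg-like 0.614 (R1/U), macrophage-like 2.65 (R1/U), 2.5 (C1/U), 0.942 (C1/R1), monocyte-like 0.977 (R1/U), 1.03 (C1/U) and CD8 T-like 1.92 (C2/R2). At Leiden resolution 0.5, share ratios were macrophage-like 1.26 (R1/U), 1.31 (C1/U) and monocyte-like 0.868 (C1/U). At Leiden resolution 2, share ratios were macrophage-like 2.03 (R1/U), 1.63 (C1/U), 0.804 (C1/R1) and monocyte-like 0.932 (R1/U), 1.00 (C1/U), 0.830 (C2/R2). There the gene counts were 9 (C1/R1) higher in macrophage-like cells and 3 (C1/R1) lower in macrophage-like cells. There the gene ratios turned to 1.04 (R1/U), 1.203 (C1/U) for Fabp4 in macrophage-like cells, 1.23 (R1/U) for Gdf15 in macrophage-like cells, 0.849 (R2/R1) for Pmaip1 in macrophage-like cells and 1.07 (C2/C1) for Rsad2 in macrophage-like cells. With 4000 variable genes, share ratios were macrophage-like 1.73 (R1/U), 1.83 (C1/U) and monocyte-like 1.17 (R1/U), 1.25 (C1/U), 0.836 (C2/R2). With myeloid-marker sub-clusters kept, share ratios were CD8 T-like 0.433 (C1/U), 1.45 (C1/R1), 6.76 (C2/C1). At 10 CPM, gene counts were 213 (R1/U), 472 (C1/U), 102 (C1/R1), 75 (C2/R2) higher in macrophage-like cells, 453 (R1/U), 546 (C1/U), 14 (C1/R1), 53 (C2/R2) lower in macrophage-like cells, 272 (R1/U), 501 (C1/U), 240 (C1/R1), 284 (C2/R2) higher in CD8 T-like cells and 354 (R1/U), 603 (C1/U), 200 (C1/R1), 532 (C2/R2) lower in CD8 T-like cells. At a ratio of 2, gene counts were 34 (R1/U), 79 (C1/U), 2 (C1/R1), 2 (C2/R2) higher in macrophage-like cells, 50 (R1/U), 69 (C1/U), 0 (C1/R1), 1 (C2/R2) lower in macrophage-like cells, 30 (R1/U), 53 (C1/U), 12 (C1/R1), 12 (C2/R2) higher in CD8 T-like cells and 10 (R1/U), 43 (C1/U), 17 (C1/R1), 46 (C2/R2) lower in CD8 T-like cells. There 3 of 5 CD8 T-like genes (60.0%, 14.7 to 94.7) had the same sign in both tumors. With cells of equal weight, gene counts were 157 (R1/U), 232 (C2/R2) higher in CD8 T-like cells, 166 (R1/U), 221 (C2/R2) lower in CD8 T-like cells and 3 (C1/R1) lower in macrophage-like cells. There the list medians turned to -0.051 (R1/U) for Th1 and costimulation genes in CD8 T-like cells, 0.062 (R1/U), 0.001 (C1/U) for cytotoxic effector genes in NK-like cells, -0.25 (C1/U) for cell cycle genes in CD8 T-like cells, 0.061 (C1/R1) for T-cell checkpoint and exhaustion genes in NK-like cells, -0.017 (R2/R1) for dissociation stress and immediate early genes in CD8 T-like cells, -0.51 (R2/R1) for cytotoxic effector genes in Treg-like cells and -0.16 (R2/R1) for p53 and DNA damage response genes in Treg-like cells. With each cell thinned to 1000 UMIs, gene counts were 181 (R1/U), 231 (C2/R2) lower in CD8 T-like cells, 75 (C1/R1), 51 (C2/R2) higher in macrophage-like cells, 19 (C1/R1), 47 (C2/R2) lower in macrophage-like cells and 293 (C2/R2) higher in CD8 T-like cells. There the gene ratios turned to 0.747 (C1/U) for Rrm2 in CD8 T-like cells, 1.09 (C1/U) for Cd274 in NK-like cells, 0.631 (C1/R1) for Nfkbid in CD8 T-like cells, 1.03 (C1/R1) for Slc17a6 in CD8 T-like cells and 1.40 (C2/C1) for Ccng1 in NK-like cells. With TMM factors, gene counts were 3 (C1/R1) lower in macrophage-like cells. There the list medians turned to 0.038 (R1/U) for cytotoxic effector genes in NK-like cells. Without the naive-led CD8 sub-cluster, gene counts were 19 (C2/R2) higher in CD8 T-like cells and 47 (C2/R2) lower in CD8 T-like cells. There the gene ratios turned to 0.914 (R2/R1) for Lef1 in CD8 T-like cells and 0.666 (R2/R1) for Dapl1 in CD8 T-like cells. There the list medians turned to -0.061 (C2/R2) for cytotoxic effector genes in CD8 T-like cells, -0.02 (C2/R2) for T-cell checkpoint and exhaustion genes in CD8 T-like cells, -0.037 (C2/R2) for Treg effector genes in CD8 T-like cells and -0.38 (R2/R1) for naive and memory T-cell genes in CD8 T-like cells. With lists at 5 CPM, list medians turned to -0.066 (C2/C1) for cytotoxic effector genes in NK-like cells. That the number of genes grows at 10 CPM and shrinks at a ratio of 2 follows from the rule, and for every other setting the cause was not tested.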

Other observations

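Of the tests that bear on these observations, those on the CD8 T-like share and on B-like and naive-led cells were chosen only after the results were seen. With anti-CTLA4 the number of CD8 T-like cells per Treg-like cell was higher in both tumors, at 5.81 against 1.66 in tumor 1 and 8.19 against 2.91 in tumor 2. In tumor 1 the Treg-like share was 3.0-fold lower, on 36 and 155 cells. The unnamed sub-cluster 15 held 61 and 9 cells there and was counted in neither class. Its leading genes included Ctla4 and Tnfrsf4 but also histone genes, Top2a and Ppbp. The CD8 T-like share there was 3.36% against 2.89%, a ratio of 1.16 (0.971 to 1.39). It was 1.64 (1.23 to 2.19) with stricter cell filters, so a rise in that share is not ruled out. It was 1.45 (1.23 to 1.71) with myeloid-marker sub-clusters kept, but this counts sub-cluster 15 as CD8 T-like. That sub-cluster had 0 markers of the class among its leading genes, as had sub-clusters 12 and 13, which were named CD8 T-like throughout. In tumor 2 the CD8 T-like share was 2.07-fold higher and the Treg-like share 1.36-fold lower.

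In tumor 2, Cxcl9, which attracts T cells and is induced by interferon-gamma, was 3.46-fold higher in macrophage-like cells of the library with the larger CD8 T-like share. In tumor 1, macrophage-like cells after radiation had 2.30-fold lower Cxcl9 along with a 3.42-fold lower CD8 T-like share. Across libraries the order was not kept, as the radiation library of tumor 2 had 280 CPM of Cxcl9 with 14.1% CD8 T-like cells and the untreated library of tumor 1 406 CPM with 9.90%. No link between the CD8 T-like share and Cxcl9 was tested.

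Tumor 2 with CTLA4 blockade held fewer CD8 T-like cells with naive genes, and the higher cell cycle genes of the class may in large part follow from that. Without the naive-led sub-cluster the cell cycle median was 0.18 instead of 0.65. The counts of genes higher and lower were then 19 and 47 instead of 108 and 140. The Pdcd1 ratio was then 1.42, below the size rule, so part of its difference remained. Gzmc and Rora stayed over 2-fold higher, at 2.94-fold and 2.47-fold. Replicate libraries of single tumors, with the irradiated side and the site recorded, would allow a test of each contrast against the spread between mice.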
